A study of Mus musculus with 6 samples.

How the data were processed

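RNA was measured in 6 samples of EGFP-positive cells from mouse embryos at E11.5, 3 from Pax2 heterozygotes and 3 from Pax2 nulls, with the genotype of each sample taken from its label. The cells were sorted by fluorescence from suspensions of the intermediate mesoderm region. Per the labels' protocols, cDNA was amplified from 10 ng of total RNA with the NuGEN WT-Pico Ovation kit, end-labelled with biotin and hybridized to a 1-colour Affymetrix mouse expression array. The deposited values are on a log2 scale, with 1 value per probe set and array, and affy, RMA and limma are named without versions in the submitters' processing notes. RMA corrects background, equalizes the distribution of values between arrays and summarizes the probes of a probe set. The settings used are not given in the sources used here. Equalized distributions hide any difference in total RNA per cell, and differences between dim probe sets are compressed towards 0.

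The table held 45101 probe sets, of which 64 were array controls. The platform annotation listed 35890 of them, 34958 with exactly 1 gene symbol and 932 with several. The other 9211 were not listed and were left unnamed. The gene identifiers of 34754 of the probe sets with 1 symbol matched a RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Its gene positions served only to order the tested genes on each side of Pax2. Each gene was represented by its probe set with the highest mean over the 6 arrays, which gave 18194 genes, 9012 of them with more than 1 probe set to choose from. No filter on dim probe sets was applied. Pax2 itself is not analysed here, so the genotype labels could not be checked against the targeted gene.

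Null and heterozygote arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, two-sided, no covariates), with Benjamini-Hochberg adjustment over the 18194 genes and a threshold of 0.05. Changes are null minus heterozygote. Errors of means are SDs over 3 arrays, and errors of changes are standard errors (SE) from the fit. Gene lists were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 34 lists that had at least 5 measured genes. The 35 lists covered kidney lineages, other cell types that the dissection or sort could hold, pathways, Hox genes and general cell functions. They were written before the data were examined, as were the tests, most of the alternatives and the rule for named genes. That rule took a fixed set of key regulators, the 12 largest rises and the 12 largest falls among changed genes whose arrays did not overlap between genotypes, and up to 4 members with the smallest p in each list. Genes named outside this rule were chosen after their values were seen, and are introduced as members of a count or marked as such. For genes with several probe sets, the named genes whose probe sets differ in sign are given with that fact.

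Nothing in the labels says that the samples came from separate litters or animals, so p-values measure only the spread between these samples, which may be partly technical. Null 1, with Xist at 4.02, and heterozygote 2, with Eif2s3y at 3.92, stood apart in sex-linked genes from the other arrays of their genotype. They were thus not repeats of the same RNA as those, while for the remaining arrays this is not known. No 2 arrays of a genotype were copies of each other, with correlations between 0.976 and 0.991 over all probe sets. The number of arrays limits the precision. The labels give no batch. The 14 probe sets for bacterial transcripts that serve as hybridization controls were therefore used, without reference to genotype, to match the 6 arrays into 3 pairs. The best of 15 matchings had a summed distance of 1.94 against 5.05 for the next, and each pair held 1 array of each genotype. Pair 1 joined heterozygote 1 and null 3, pair 2 heterozygote 2 and null 1, and pair 3 heterozygote 3 and null 2. After removal of the genotype means, the arrays of a pair correlated at 0.377 or more across genes, whereas arrays of opposite genotype from different pairs reached at most 0.097. This pairing was found in the data and is not in the labels, and fits with the pair as a block were added after the data were seen.

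The alternatives were an intensity-dependent prior, a robust prior, a filter at the 33rd percentile, renewed quantile normalization, median centring, array weights, omission of each array, the mean over a gene's probe sets, all probe sets as units, thresholds of 0.01 and 0.10, a limit of 2-fold, an unmoderated linear model, the pair block (for lists in camera with either correlation and in fry) and omission of each pair. The fits were tested on simulated data with the means and spreads of the 18194 genes and 200 changed genes. With independent arrays, limma without a block called 34% of genes changed by 1 log2 unit, 86% at 2 units, 92% at 3 units and 100% at 4 units, with 11 unchanged genes called. With simulated pairs, the fit without a block called 42%, 86%, 92% and 100%, with 4 unchanged genes called. The block fit on simulated pairs called 52%, 94%, 100% and 100%, with 1 unchanged gene called. Camera recovered a simulated list of 25 genes shifted by 1 unit and called 0 of 34 unshifted lists. The genes were simulated as independent of each other, so this could not show false calls from correlated list members. Estimated correlations within the real lists reached 0.562. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.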

Results

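Cells expressing EGFP were sorted from the intermediate mesoderm region of mouse embryos at E11.5, and their RNA was profiled on 6 arrays, 3 from Pax2 heterozygotes and 3 from Pax2 nulls. Pax2 encodes a transcription factor of the developing kidney, and the intermediate mesoderm gives rise to the kidneys and gonads. The sample titles give 1 EGFP allele in heterozygotes and EGFP on both alleles in nulls, so the comparison is between null and heterozygous cells and includes no wild-type sample. Median log2 values lay between 6.12 and 6.24 in the 6 arrays. The arrays fell into 3 pairs by their hybridization controls, with mean bioB levels of 10.52 and 10.55 in pair 1, 7.81 and 8.20 in pair 2, and 7.24 and 7.23 in pair 3 (log2).

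The design asked which genes depend on Pax2 in this tissue. In null cells, genes of the nephric duct and of the metanephric mesenchyme were lower, while genes of stroma, extracellular matrix and macrophages were higher. Of these 5 lists, only the stromal list passed camera in limma with an estimated correlation (adjusted p = 0.0400), against 0.106 for the duct and the mesenchyme, 0.0921 for matrix and 0.221 for macrophages. None did once the array pair was also a block (adjusted p = 0.399 to 0.440). That fit leaves few residual degrees of freedom, on which this test rests, so hardly any list could pass and the loss decides nothing. They are also few without the block, so a call lost there is not by itself a sign of correlated members. In total 253 of 18194 genes changed (limma, adjusted p under 0.05), 147 higher and 106 lower in null, and 245 of them by at least 2-fold. The median size of these changes was 1.61 on the log2 scale. All 253 had arrays that did not overlap between genotypes, as did 13.6% of all genes where chance gives 10%. The count fell to 98 without heterozygote 2, 84 without heterozygote 3, 86 without null 1 and 110 without null 2, and was 551 with array weights and 3 without moderation of the variances. With the pair as a block, 824 genes changed, 482 higher and 342 lower, including all 253, whereas 251 genes passed without pair 1, 1 without pair 2 and 2 without pair 3.

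**Figure D1:**
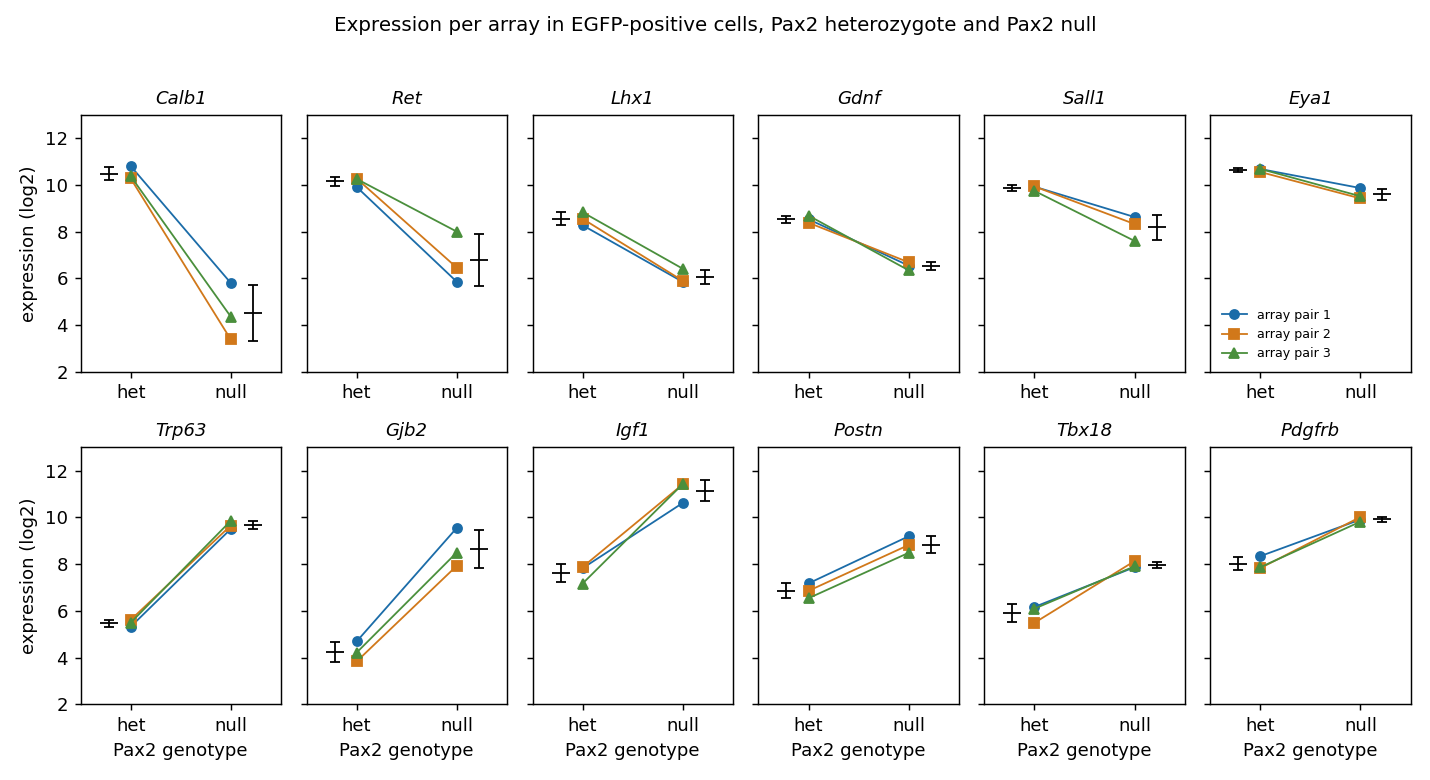
Expression (log2) of 12 genes on each array, heterozygote on the left and null on the right of each panel, with lines joining the arrays of a pair and black bars giving the mean and SD of 3 arrays. The upper 6 genes were lower and the lower 6 genes higher in null in all 3 pairs, from 10.49 to 4.52 on average for Calb1 and from 5.47 to 9.67 for Trp63.

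Nephric duct and ureteric bud genes, which mark the epithelium that forms the collecting ducts, were lower in null cells. Calb1, which encodes a calcium-binding protein of the duct, went from 10.49 ± 0.28 in heterozygotes to 4.52 ± 1.22 in nulls (log2, SD, n = 3 each), the largest measured fall among the genes that passed. Ret, the duct receptor for Gdnf, went from 10.15 ± 0.20 to 6.77 ± 1.11, a 10.4-fold fall. Mal, a membrane proteolipid, changed by -3.33 ± 0.29 (SE), and the transcription factors Lhx1, Elf5 and Gata3 by -2.50 ± 0.22, -2.42 ± 0.42 and -1.40 ± 0.21. Of 27 measured members of the list, 6 fell and 0 rose, and adjusted over the list alone 12 fell and 3 rose. With the pair as a block 11 fell and 3 rose, the latter being Krt19 (1.21), Tfap2a (0.75) and Tfap2b (1.19). Of the keratin and adhesion genes in the same list, Epcam, Krt8 and Krt18, picked after their values were seen, stood near 0 and did not pass, with changes of -0.06 ± 0.16 for Epcam, -0.05 ± 0.25 for Krt8 and -0.05 ± 0.25 for Krt18. The adhesion gene Cdh16 had a change of -1.28 ± 0.28 that did not pass (limma, adjusted p = 0.0888) but did with the block (0.00911). The list had a median change of -0.71 (camera in limma, adjusted p = 3.78e-09), with adjusted p = 0.106 with an estimated correlation and a range over the alternatives of 1.09e-10 to 0.399. In fits with 1 array left out, limma's adjusted p stayed under 0.05 for Calb1, Mal and Lhx1. It reached 0.0857 for Ret without heterozygote 2, heterozygote 3 or null 1, and 0.0945 for Gata3 without heterozygote 2, heterozygote 3, null 1 or null 2, and 0.145 for Elf5 without heterozygote 3, null 1 or null 2.

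The ligand Gdnf, which is made by the metanephric mesenchyme and draws out the ureteric bud, fell with its receptor. Gdnf went from 8.53 ± 0.15 to 6.53 ± 0.17 (log2, SD, n = 3 each), a 4.01-fold fall (limma, adjusted p = 0.00332). Among 17 measured genes of the Gdnf-Ret pathway and its targets, Gdnf and Ret fell and the other 15 did not pass. Gfra1, the co-receptor, had a change of -1.60 ± 0.30 (limma, adjusted p = 0.0509), Dusp6 of -0.90 ± 0.18 and Etv5 of -0.71 ± 0.15, and with the pair as a block these 3 were among 8 genes that fell. Adjusted over the list alone, 6 fell. The list's median change was -0.55 (camera in limma, adjusted p = 4.14e-08), and its call held with an estimated correlation (adjusted p = 0.0400) and in fry (adjusted p = 0.00559). With the pair as a block it held in fry (adjusted p = 0.0157). Limma's camera with an estimated correlation, which can hardly pass any list with the block, gave an adjusted p of 0.399. The range over the alternatives was 1.99e-09 to 0.399. The Gdnf-Ret list shares 6 of its measured genes with the duct list.

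Genes of nephron progenitors and the metanephric mesenchyme were lower in null, with 5 of 20 measured members falling. Sall1 went from 9.87 ± 0.11 to 8.18 ± 0.53 and Eya1 from 10.64 ± 0.07 to 9.60 ± 0.23 (log2, SD, n = 3 each). Bmp7, a signal that maintains progenitors, changed by -1.31 ± 0.22 (SE) and Traf1 by -1.49 ± 0.19. Cited1, a transcriptional co-regulator of early progenitors, rose by 1.76 ± 0.33, against the direction of the list. Six2, which keeps progenitors from differentiating, had a change of -1.13 ± 0.30 that did not pass (limma, adjusted p = 0.169), though it passed with the pair as a block (adjusted p = 0.0190, in a range over the alternatives from 0.0190 to 0.933). Hoxa11 (-0.68 ± 0.16) likewise had a limma adjusted p of 0.103 without and 0.0295 with the block, in a range from 0.0281 to 0.705. Osr1 (-0.81 ± 0.49), Hoxd11 (-0.28 ± 0.37) and Wt1 (-0.09 ± 0.15) did not pass either way, nor did Emx2 (-0.43 ± 0.17), a key regulator from the duct list. Adjusted over the list alone, 12 members fell and 1 rose. The list's median change was -0.78 (camera in limma, adjusted p = 1.13e-11), with adjusted p = 0.106 with an estimated correlation and a range over the alternatives of 8.33e-15 to 0.399. With 1 array left out, limma's adjusted p reached 0.0947 for Sall1 (lost without heterozygote 2, heterozygote 3 or null 1) and 0.0508 for Traf1 (without heterozygote 3). It reached 0.129 for Eya1, 0.137 for Bmp7 and 0.150 for Cited1, each lost in every such fit but that without null 3.

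The Pax-Eya-Six-Sall-Hox11 list of regulators, with the PTIP complex, shares 7 of its 15 measured genes with the progenitor list, and 4 of the 15 fell, namely Eya1, Sall1, Lhx1 and Gata3. Adjusted over the list alone, 7 fell, and the median change was -0.68, or -0.44 without null 3 (camera in limma, adjusted p = 4.14e-08). This call held with an estimated correlation (adjusted p = 0.0400) and in fry (adjusted p = 0.00218). With the pair as a block it was lost in limma's fry (adjusted p = 0.0578), which also rests on the few residual degrees of freedom that the block leaves. Camera with an estimated correlation, which can hardly pass any list with the block, gave an adjusted p of 0.399. The range over the alternatives was 7.36e-09 to 0.399. Pax8, the close relative of Pax2, went from 9.47 ± 0.11 to 8.27 ± 0.85 and did not pass (limma, adjusted p = 0.263). Paxip1, which encodes PTIP, had a change of 0.02 ± 0.18, and only 1 of its 4 probe sets had that sign. Among 18 measured genes of early nephrons and mesonephric tubules, Lhx1, Irx1 (-1.47 ± 0.17) and Irx3 (-1.42 ± 0.24) fell and Cdh6 rose (1.61 ± 0.20), and adjusted over the list alone 8 fell and 3 rose. Wnt4, a trigger of nephron formation, had a change of 0.62 ± 0.19 and did not pass (limma, adjusted p = 0.242). This list's median change was -0.34, and -0.17 without heterozygote 1 (camera in limma, adjusted p = 0.0237), and its call was lost with an estimated correlation (adjusted p = 0.180), with the pair block (0.0690), without heterozygote 1 (0.0838) and without null 3 (0.0549), in a range from 0.00384 to 0.440. With 1 array left out, limma's adjusted p stayed under 0.05 for Irx1 but reached 0.0571 for Cdh6 (without heterozygote 2 or 3) and 0.108 for Irx3 (lost in all such fits but that without null 1).

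Beyond these lists, the 12 largest falls included Plet1 (-3.46 ± 0.21, SE), which encodes a surface protein of epithelial progenitors, and the imprinted noncoding RNA Ipw (-3.44 ± 0.24). They also included Cltrn (-3.19 ± 0.38), Anks1b (-3.03 ± 0.41), the cell adhesion molecule L1cam (-2.95 ± 0.44), the carbonic anhydrase Car4 (-2.89 ± 0.40), Chst13 (-2.76 ± 0.33), Mal2 (-2.71 ± 0.42) and Ipcef1 (-2.61 ± 0.25). The largest measured rise was in Cxcl15, a chemokine, from 5.20 ± 0.52 to 9.83 ± 0.61 (log2, SD, n = 3 each). Gjb2, a gap junction protein, went from 4.24 ± 0.43 to 8.65 ± 0.82, and Trp63, a regulator of basal and stratified epithelia, from 5.47 ± 0.15 to 9.67 ± 0.18. Trp63 had the smallest adjusted p of these rises (limma, adjusted p = 0.000134), and 3 of its 4 probe sets passed. The growth factor Igf1 rose by 3.53 ± 0.28, the Wnt inhibitor Wif1 by 3.17 ± 0.25, Wnt3 by 2.97 ± 0.35, the endodermal regulator Foxa2 by 2.94 ± 0.28 and Tmem132c by 2.78 ± 0.23. Lum, Stmn2, Cpz and Ephx1 completed the 12, with rises of 2.69 ± 0.39, 2.64 ± 0.47, 2.60 ± 0.26 and 2.50 ± 0.36. The lower mean of Calb1, Ipw, Cltrn, Anks1b, Ipcef1, Gjb2, Wif1, Wnt3, Foxa2 and Lum lay under the 33rd percentile of all probe sets (4.81). Differences are compressed there, which would understate the sizes, while the choice of the largest changes would overstate them. Both the sizes and the order of the changes are therefore uncertain. Of the 54 named genes that passed, 24 passed in all 6 fits with 1 array left out. The calls of L1cam (without heterozygote 2, heterozygote 3 or null 3, limma adjusted p up to 0.0932), Car4 (heterozygote 2 or null 1, 0.0636) and Anks1b (heterozygote 2, heterozygote 3 or null 1, 0.0739) were lost. So were those of Mal2 (heterozygote 3, null 1 or null 2, limma adjusted p up to 0.101), Lum (heterozygote 3, null 1 or null 3, 0.0855), Ephx1 (heterozygote 2, heterozygote 3, null 2 or null 3, 0.0863) and Stmn2 (heterozygote 1 or any null array, 0.141).

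Stromal genes were higher in null cells, 24 of 25 measured members having a positive change. Tbx18, a transcription factor of stromal and ureteric mesenchyme, went from 5.91 ± 0.37 to 7.97 ± 0.14, Pdgfrb, a receptor of perivascular and stromal cells, from 8.01 ± 0.29 to 9.91 ± 0.10, and the matrix protein gene Postn from 6.86 ± 0.32 to 8.83 ± 0.35 (log2, SD, n = 3 each). With Col1a2, Dcn and Lum, 6 members rose and 0 fell, and adjusted over the list alone 18 rose. Foxd1, the marker of cortical stroma, had a change of 0.55 ± 0.19 that did not pass (limma, adjusted p = 0.351). The list's median change was 0.91 (camera in limma, adjusted p = 5.64e-20), and its call held with an estimated correlation (adjusted p = 0.0400) and in fry (adjusted p = 0.00559). Under the pair block, the stromal call was lost in fry (adjusted p = 0.0578), which also rests on the few residual degrees of freedom left. Limma's camera with an estimated correlation, which can hardly pass any list with the block, gave an adjusted p of 0.399. The range over the alternatives was 8.52e-22 to 0.399. Extracellular matrix genes followed, sharing 6 measured genes with the stromal list. Of 36, Col1a2, Col12a1, Nid2, Bgn, Dcn, Lum and Postn rose and 0 fell, adjusted over the list alone 21 rose and 2 fell, and the median change was 0.75 (camera in limma, adjusted p = 2.85e-14, and adjusted p = 0.0921 with an estimated correlation, in a range from 1.05e-16 to 0.399). Tbx18, Pdgfrb and Postn passed in every fit with 1 array left out, whereas limma's adjusted p reached 0.0601 for Col1a2 (without null 1), 0.0823 for Dcn (without heterozygote 2 or 3) and 0.0855 for Lum (without heterozygote 3, null 1 or null 3). It reached 0.0969 for Col12a1, 0.1001 for Nid2 and 0.128 for Bgn, each lost without heterozygote 2, heterozygote 3, null 1 or null 2, and Nid2 and Bgn also without null 3.

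All 16 measured macrophage and leukocyte genes had a positive change, with a median of 1.17, and pair medians of 0.72, 1.18 and 1.85. No member passed over all genes, whereas 7 rose when adjusted over the list alone and 5 with the pair as a block, among them Tyrobp (1.49 ± 0.39) and Laptm5 (1.28 ± 0.33). Mrc1, a macrophage scavenger receptor, had a change of 2.39 ± 0.57 (limma, adjusted p = 0.117). Camera in limma gave an adjusted p of 4.89e-10 for the list, but adjusted p = 0.221 with an estimated correlation, the estimated correlation of its members being 0.528, and adjusted p = 0.148 in fry, in a range from 5.92e-17 to 0.440. Gonad and adrenal genes were also higher, with 13 of 14 measured members positive and a median of 0.63 (camera in limma, adjusted p = 2.87e-07, and adjusted p = 0.0921 with an estimated correlation, in a range from 5.82e-08 to 0.399). Among them the steroidogenic enzyme gene Hsd3b1 rose by 2.26 ± 0.27, while Nr5a1 (1.83 ± 0.40) and Gata4 (1.45 ± 0.43) did not pass over all genes (limma, adjusted p = 0.0926 and 0.224) but did with the block. Adjusted over the list alone, 5 rose. Hsd3b1 had a limma adjusted p of 0.0543 without heterozygote 3.

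Retinoic acid pathway genes had a median change of 0.55, or 0.36 without null 2 (camera in limma, adjusted p = 0.000505, but adjusted p = 0.166 with an estimated correlation and 0.0719 in fry, in a range from 5.90e-05 to 0.399). Crabp1, which binds retinoic acid, rose by 1.84 ± 0.24 and its receptor Rarg by 1.01 ± 0.18, the other 13 of 15 not passing over all genes, and adjusted over the list alone 4 rose and 1 fell. Aldh1a3, also in the duct list, had a change of -1.47 ± 0.29 (limma, adjusted p = 0.0606, and 0.0285 with the pair block). All 3 of its probe sets were negative, and 2 passed when probe sets were tested singly. Rarg passed in no fit with 1 array left out (limma, adjusted p up to 0.165), and Crabp1 was lost without heterozygote 2, heterozygote 3, null 1 or null 2 (up to 0.0739). Among 19 genes of the BMP and TGF-beta pathway, Bmp5 (1.09 ± 0.16) and Msx1 (1.60 ± 0.27) rose and Bmp7 fell, with 3 rising and 2 falling when adjusted over the list alone, and the list's median was 0.24, or 0.40, 0.16 and 0.40 without heterozygotes 1, 2 and 3 (camera in limma, adjusted p = 0.00293, and adjusted p = 0.106 with an estimated correlation). Among 16 Wnt-beta-catenin targets, the Wnt inhibitors Wif1 and Notum (1.58 ± 0.20) rose and the receptor gene Lgr5 (-1.22 ± 0.18) fell, and adjusted over the list alone 2 rose and 2 fell. The median of these targets was 0.21, or 0.34, 0.12 and 0.32 without heterozygotes 1, 2 and 3 (camera in limma, adjusted p = 0.0221, and adjusted p = 0.166 with an estimated correlation), and their call was lost without null 1 (adjusted p = 0.0501). Wif1 passed in all 6 fits with 1 array left out. Notum was lost without heterozygote 2, heterozygote 3, null 1 or null 2 (limma, adjusted p up to 0.0646), Bmp5 (0.0991), Msx1 (0.117) and Lgr5 (0.0980) in all such fits but that without heterozygote 1, and Bmp7 (0.137) in all but that without null 3.

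A further 5 lists passed camera, and none of them held with an estimated correlation. Neuronal genes had a median of 0.10 (camera in limma, adjusted p = 0.00537, and adjusted p = 0.311 with an estimated correlation). This median was 0.06 without heterozygote 1 or null 1, 0.15 without heterozygote 2, 0.05 without null 2 and 0.18 without null 3. In this list Stmn2, Nefm (1.44 ± 0.17) and Map2 (1.90 ± 0.32) rose and Elavl4 (-1.54 ± 0.29) fell among 24. Adjusted over the list alone, 4 rose and 1 fell. Epithelial junction and keratin genes had a median of -0.21, which was -0.05 without heterozygote 1 or null 1 and -0.35 and -0.34 without heterozygote 2 and null 2 (camera in limma, adjusted p = 0.00759, and adjusted p = 0.655 with an estimated correlation). Cldn8, a tight junction gene of the collecting duct, fell by 1.81 and was the 1 of 29 that passed, with 1 rising and 2 falling adjusted over the list alone. The Hox genes of groups 4 to 8 had a median of 0.31 (camera in limma, adjusted p = 0.0368, and adjusted p = 0.392 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.15 (camera in limma, adjusted p = 0.00870, and adjusted p = 0.339 with an estimated correlation), and cell cycle genes a median of -0.14, or -0.09 without heterozygote 2 (camera in limma, adjusted p = 0.0299, and adjusted p = 0.339 with an estimated correlation). In these last 3 lists 0 genes passed, either over all genes or adjusted over the list alone. Fits with 1 array left out raised the adjusted p of these 5 lists to 0.105, 0.416, 0.400, 0.115 and 0.134 in the order given, with losses without heterozygote 1 (all but hypoxia), null 1 (epithelial, Hox and cell cycle), heterozygote 2 and null 3 (cell cycle) and heterozygote 3 (hypoxia). Nefm passed in all 6 of these fits, Map2 (limma, adjusted p up to 0.120) and Elavl4 (0.182) only in that without heterozygote 1, Cldn8 (0.111) only in that without null 3, and Stmn2 (0.141) only without heterozygote 2 or 3.

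The other 17 lists did not pass. Leaving the Y-linked genes aside, the 16 had medians between -0.17 and 0.40 and camera adjusted p between 0.0558 and 0.903 in limma. The highest, of red blood cells, was 0.71 without heterozygote 1, -0.01 without heterozygote 2 and 0.19 without null 2. The lowest, of Hox genes of groups 9 to 13, was -0.11 without heterozygote 2 and -0.12 without null 3. They were the lists of paraxial mesoderm, skeletal muscle, cartilage, neural crest, endothelium, red blood cells, germ cells, mesothelium, gut endoderm and liver, limb and lateral mesoderm, Notch, Hox genes of groups 9 to 13, p53 targets, immediate early genes, ribosomal proteins and the respiratory chain. Genes that passed within them were Tbx18, Podxl (1.72 ± 0.27), Foxa2, Prrx2 (1.19 ± 0.17) and Msx1, which rose, and Meox2 (-1.77 ± 0.22) and Phox2a (-1.26 ± 0.22), which fell. With 1 array left out, Podxl (limma, adjusted p up to 0.101), Prrx2 (0.0864) and Msx1 (0.117) passed only without heterozygote 1, and Phox2a (0.129) only without null 2. In 4 of these lists (paraxial mesoderm, mesothelium, gut endoderm and Notch) the median, mean and test differed in sign. Camera's adjusted p in limma was lowest, with 1 array left out, at 0.0208 for the limb list, 0.0117 for posterior Hox genes and 0.00573 for immediate early genes, in ranges up to 0.606, 0.606 and 0.982 over all alternatives. Among sex-linked genes, Xist was at 4.02 in null 1 and at least 8.84 in the other 5 arrays, and Eif2s3y was at 3.92 in heterozygote 2 and at least 7.90 in the other 5. Neither passed, with changes of -3.13 ± 1.46 for Xist and 1.52 ± 1.06 for Eif2s3y, and the 5 measured Y-linked genes had a median of 1.50 (camera in limma, adjusted p = 0.0848). Without heterozygote 2 this median was 0.09 (adjusted p = 0.256), and without heterozygote 3 it was 2.21 and the list passed (camera in limma, adjusted p = 0.00673).

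**Figure D2:**
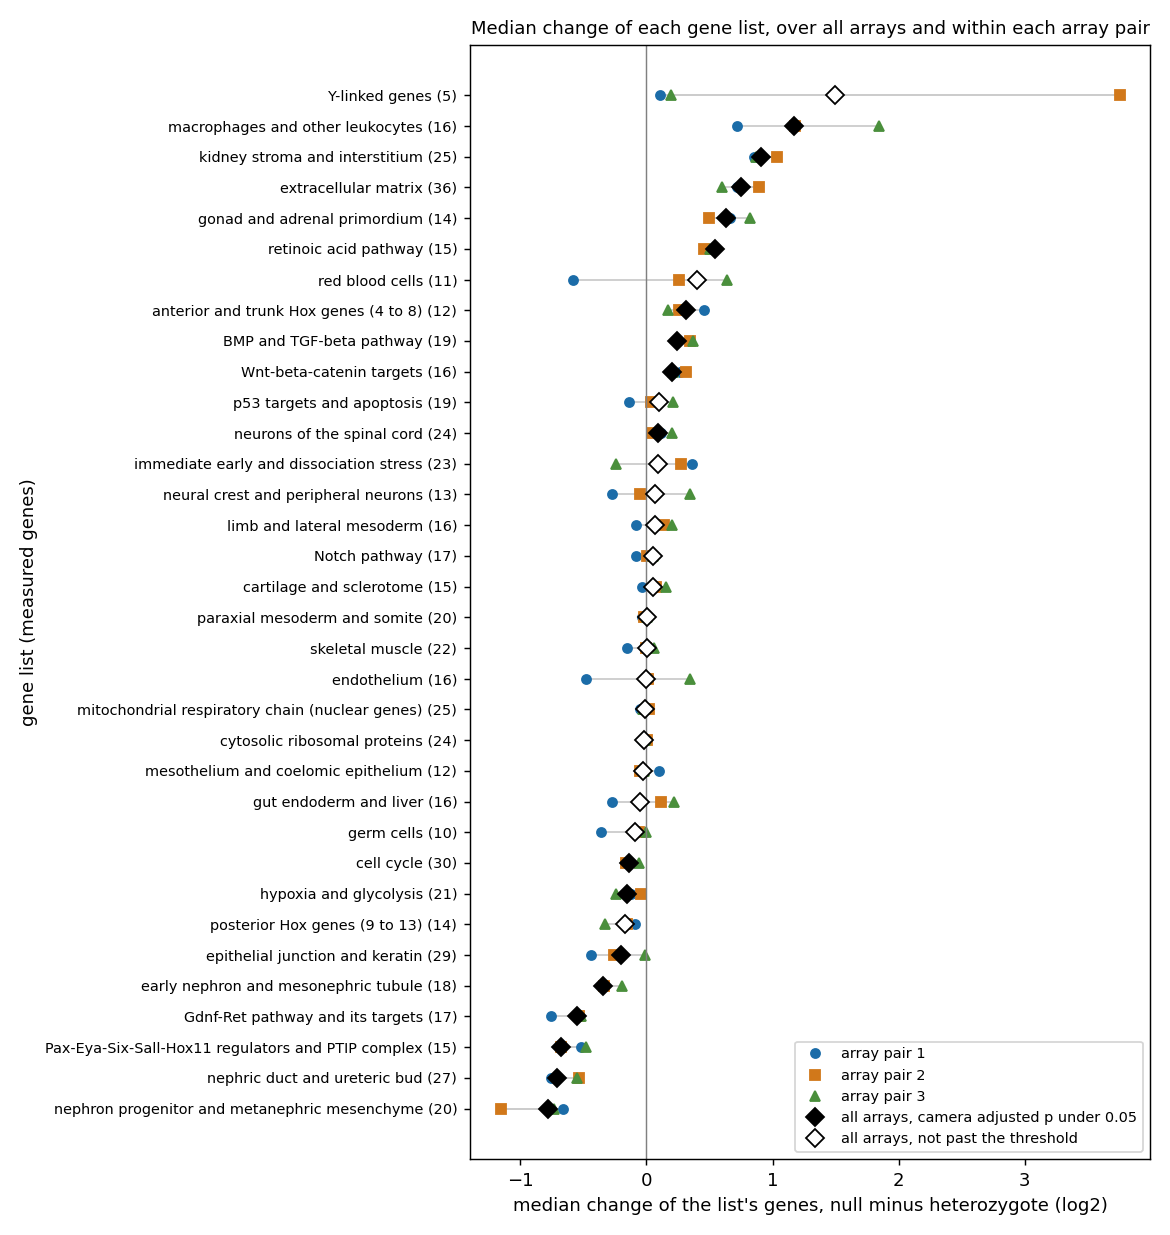
Median change of each gene list, null minus heterozygote (log2, horizontal axis), with diamonds for all 6 arrays (filled where camera's adjusted p was under 0.05), coloured points for the 3 array pairs, and the number of measured genes in brackets. The duct and progenitor lists lie below 0 (medians -0.71 and -0.78) and the stromal, matrix and macrophage lists above 0 (0.91, 0.75 and 1.17) in all 3 pairs, while red blood cell and endothelial lists lie on both sides of 0.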

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

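The fits with the array pair as a block or without a pair were chosen after the result was seen, and the other alternatives before the data were examined. The 253 genes became between 239 and 287 with the other priors, the filter on dim genes and both further scalings, 245 with the limit of 2-fold, 368 with the mean over probe sets and 311 probe sets when all were counted. Bmp7, Lgr5 and Traf1 lost their calls with the mean over probe sets. Changes of single probe sets ranged from 0.19 to 1.56 for Dcn, 0.30 to 1.60 for Msx1 and -1.22 to -0.27 for Lgr5. They ranged from -3.03 to -0.15 for Anks1b and from -2.61 to -0.34 for Ipcef1. Larger moves were 551 with array weights, 824 with the pair block and 490 with the block and at least 2-fold, and 51 and 405 at thresholds of 0.01 and 0.10, which differ by construction. Without moderation of the variances 3 genes passed, and 1 and 2 without pair 2 and pair 3, against 251 without pair 1. With 1 array left out the count ranged from 84 to 318, being highest without heterozygote 1, and the cause was not tested. Both arrays of pair 1 had low array weights, 0.404 for heterozygote 1 and 0.532 for null 3, against 1.09 to 1.97 for the others. The number of lists past the threshold was 17 in the camera test and 13 to 19 with 1 array left out, but 3 with an estimated correlation and 9 in fry. With the pair block it was 16 in camera, 1 in fry and 0 with an estimated correlation. Camera with an estimated correlation rests on the residual degrees of freedom, which are few without the pair block and fewer with it. With the block hardly any list could pass, so the loss in that test is no evidence for or against a shift. Without the block, lists with an estimated correlation under the preset 0.01 weakened too. Camera's adjusted p in limma went from 4.14e-08 to 0.0400 for Gdnf-Ret genes (correlation -0.03). For early nephron genes (0.006) it went from 0.0237 to 0.180. A call lost with an estimated correlation is therefore not by itself a sign of correlated members. The cause of the other differences was not tested. Estimated correlation gave an adjusted p of 0.106 for the progenitor and duct lists, 0.180 for early nephron genes, 0.221 for macrophages, 0.0921 for the gonad and matrix lists and 0.166 for retinoic acid. Fry gave 0.148 for macrophages and 0.0719 for retinoic acid. Estimated correlation with the pair block gave 0.440 for early nephron genes and macrophages and 0.399 for the other 8 lists described first. Fry with the block gave 0.145 for macrophages, 0.0615 for gonad genes, 0.0828 for retinoic acid and 0.0578 for the rest except Gdnf-Ret, which kept its call (adjusted p 0.0157). Fry rests on the residual degrees of freedom as well, so a threshold missed there with the block is weak evidence against a shift. Early nephron genes also missed the threshold with array weights (adjusted p 0.0627), the pair block (0.0690) and without pair 1 (0.178), and ranged from 0.0156 to 0.0838 with 1 array left out. No alternative turned the direction of a call. Of 2728 values of named genes under the alternatives 291 calls were lost and 84 gained, and of 479 for the other 24 lists 45 were lost and 14 gained. The 2728 include named genes that had no call to lose. Of the 54 named genes that passed, 53 lost their call in at least 1 alternative. Many of these losses were in the unmoderated fit and in those without pair 2 or 3, where few genes passed. Only Trp63 kept its call throughout (limma, adjusted p up to 0.0475). The alternatives planned for Pax2 itself were not run, since it is not analysed here.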

Other observations

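Tests chosen only after the result was seen were the count of other splits, the comparisons of epithelial with duct genes and of stroma with other cell types, the sort gate, and the lists of urogenital and basal genes; the tests of embryo sex and of genes next to Pax2 were written before their values were seen.

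The single genes in this paragraph were picked after their values were seen. The sodium channel subunits Scnn1b and Scnn1g changed by -1.79 ± 0.25 (SE) and -2.03 ± 0.25, the ammonium transporter Rhcg by -2.51 ± 0.35, the claudin gene Cldn2 by -2.33 ± 0.36 and the endocytic receptor gene Lrp2 by -1.83 ± 0.28, and Sim1, a transcription factor, by -1.86 ± 0.16 (limma, adjusted p between 0.00338 and 0.0229). Genes that rose included Upk1a (2.32 ± 0.29), a uroplakin of bladder epithelium, the keratins Krt5 (1.78 ± 0.21) and Krt20 (1.38 ± 0.21), and Grhl3 (2.40 ± 0.41), a regulator of surface epithelium. The GATA factor genes Gata2, Gata5 and Gata6 rose by 1.21 ± 0.15, 1.93 ± 0.20 and 1.41 ± 0.17, opposite to Gata3, and the hedgehog target Gli1 rose by 1.48 ± 0.19. With 1 array left out, limma's adjusted p stayed under 0.05 for Sim1, Krt5 and Gata5. It reached 0.0675 for Scnn1b, 0.0613 for Scnn1g, 0.0678 for Rhcg and 0.0642 for Gli1 (lost without heterozygote 3, null 1 or null 2), 0.0586 for Upk1a (heterozygote 3 or null 1), 0.0591 for Gata2 (heterozygote 2 or null 1) and 0.0538 for Gata6 (null 1). For Cldn2 (heterozygote 2 or any null array), Lrp2 (heterozygote 2, heterozygote 3, null 1 or null 3), Krt20 and Grhl3 (heterozygote 2, heterozygote 3, null 2 or null 3) limma's adjusted p reached 0.0902, 0.0991, 0.0991 and 0.137. Ipw fell by 3.44, while the other 6 measured genes of its imprinted region did not pass, Magel2 and Peg12 having changes of -0.20 ± 0.26 and -0.38 ± 0.25.

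For the 253 genes as a whole, 1 of the 10 splits of the 6 arrays into 3 and 3, the real one, gave as many, and the highest other split gave 1, but 10 splits are too few for a share under 0.05, and at unadjusted p under 0.05 the real split gave 1770 genes and the 4 splits that kept pair 1 together gave 1662 to 2043, a structure of the arrays apart from genotype. The mix of embryo sexes may differ between the samples. Xist was low in null 1 and Y-linked genes were low in heterozygote 2, both of pair 2. In heterozygotes 1 and 3 and nulls 2 and 3, Xist (at least 8.84) and Eif2s3y (at least 7.90) were both high. These samples thus appear to hold cells of both sexes, and Xist also differed by -2.13 in pair 3. In pair 1, where Xist and Eif2s3y differed by 0.41 and -0.05, 247 of 251 genes called from pairs 2 and 3 went the same way, with a median ratio of 0.790 to the called change (quartiles 0.638 and 1.02). This argues against sex as the cause for these 251 genes as a set. Of them, 172 were among the 253, and the rest of the 253 were not covered. DNA carried along beside the targeted allele stays open for nearby genes: 5 of 200 tested genes, the nearest 100 on each side of Pax2, passed against 1.38% elsewhere (Fisher's exact p = 0.208, two-sided), and the odds ratio's 95% interval reached 4.40. The rule written beforehand would have excluded this explanation, but an upper limit of 2 for that interval was set after the values were seen and was not met, and 248 called genes lay outside the window. With the pair as a block, 10 of these 200 neighbours passed against 4.53% elsewhere (Fisher's exact p = 0.731, two-sided).

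Duct genes fell while Trp63, Gjb2 and Foxa2, picked from the largest changes, rose, although in the fixed junction and keratin list 24 of 29 genes were negative and 0 rose. Fewer epithelial cells in the null sort would lower general epithelial genes as much as duct genes, if other sorted cells did not express them. The 24 junction and keratin genes outside the duct list, with a mean change of -0.35, fell by 0.64 less than the 27 duct genes. The duct mean was -0.99, against a list median of -0.71, and the difference was at least 0.49 in each pair (SD 0.13 over 3 pairs). Expression of the junction and keratin genes in other sorted cells was not tested, so the difference leaves fewer epithelial cells open. A different epithelium among the null cells is a candidate explanation. Lists of further urogenital sinus and of further basal epithelial genes, written after Trp63 and Foxa2 had been seen and without the genes already seen to pass, had medians of 0.0951 (95% of resampled medians between -0.07 and 0.32) and 0.0485 (-0.27 to 0.41), and limma's camera gave p of 0.0686 and 0.399. Only 7 of 18 and 14 of 20 of these genes were above the 33rd percentile, so with a limit of 0.2 on the interval, set after the values were seen, the lists exclude nothing, and a change within the duct cells themselves is untested.

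Stromal and matrix lists were higher and progenitor and duct lists lower, with 6 of 25, 7 of 36, 5 of 20 and 6 of 27 genes passing in that direction, and apart from stroma with adjusted p of 0.0921, 0.106 and 0.106 in limma's camera with an estimated correlation. A lower share of kidney-lineage cells that raised all other types alike would lift endothelial, red blood cell, muscle, neuronal and neural crest genes with the stroma, whose change exceeded the mean of these 5 lists by 0.87 (SD 0.38 over 3 pairs; 1.12, 1.06 and 0.44 in pairs 1, 2 and 3). This stays open, because with the 51 of 86 genes above the 33rd percentile the difference was 0.77 (SD 0.46), less than 2 SDs from 0, and it was 0.54 (SD 0.44) when the macrophage and gonad lists were included, with mean changes of 1.16 and 0.76 (limma's camera, adjusted p of 0.221 and 0.0921 with an estimated correlation). A wider sort gate stays open too: null cells carry EGFP on both alleles and could pass the gate with weaker promoter activity, and the stroma median of 0.91 cannot be told apart from an effect of genotype, because EGFP copy number equals genotype in every sample. A change of fate or of gene expression in cells without Pax2 remains an open explanation as well, and macrophage list means were 0.62, 1.17 and 1.70 in pairs 1, 2 and 3.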
